A study of Homo sapiens with 24 samples.

How the data were processed

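Messenger RNA of 3 breast carcinoma lines was sequenced from 24 samples in 8 groups of 3, after transient transfection with siRNA (72 to 96 h) or in stable clones made with a lentiviral shRNA, per the labels. The labels state that the submitters did not authenticate the lines. Libraries were made with a TruSeq RNA kit, per the labels' protocols. Bowtie 0.12.2, Cuffdiff (its version is not given in the sources used here) and the builds hg19 and GRCh37 are named in the submitters' processing notes.

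The 4 files used are the authors' deposited comparison tables, 3 genome-wide and 1 of 68 selected genes. FPKM values, 1 per group with its samples pooled, are those of the authors, per the file headers. The test statistic, a score on the scale of the authors' tool, was used as deposited. The p-value and q-value of each entry are the authors' own, per the file headers. No column holds a single sample, so replicate spread, depth per sample and pairing are unknown, no model was fitted to samples, and no interval for a single FPKM can be given. Low FPKM showed no whole-read steps from which depth could be recovered. In the genome-wide tables the deposited q equalled a Benjamini-Hochberg adjustment over the tested entries, with 0 calls that differed. In the HCC1569 table it did not (largest relative difference 0.568, with 0 calls that differed), and over which entries that q was adjusted is unknown.

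The genome-wide tables hold 66321 RefSeq accessions, of which 65468 matched a gene symbol through a table of NCBI RefSeq names (GRCh38.p14, used for names alone) and 853 did not. Of 27431 symbols 12074 had more than 1 accession, and each symbol was represented by the accession with the highest mean FPKM over the 6 groups. That accession can hold little of a gene's signal in another table. Loci of the genome-wide tables overlapped the GRCh37 gene of that name (GENCODE annotation) in 97.8%, 97.7% and 97.8% of cases, and those of the HCC1569 table in 11.9%, so none of its coordinates is given. One table's columns read only non-targeting and AP2C siRNA, and it was taken as HCC1954 from the name of the deposited file, which also is the siRNA line that the other tables leave among the labels.

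A call is a deposited q under 0.05 for an entry with a completed test, and its direction is that of knockdown over control FPKM. No pseudocount enters a printed fold, and where a group is listed at 0 no fold is given. The smallest p in the tables was 5e-05. Overlaps of calls were tested with one-sided Fisher's exact tests over genes tested in both tables, with Benjamini-Hochberg adjustment over 12 tests, 6 of which, those of opposite directions, were not in the fixed design. Differences between comparisons were tested with z, the difference of log2 ratios over the root of the summed squared standard errors, each standard error being log2 ratio over deposited statistic, adjusted over the genes compared. The normal quantile of the deposited p was 2.00, 2.46 and 3.36 times the statistic in the median (SKBR3 siRNA, HCC1954 siRNA and HCC1954 shRNA), so this test calls few genes.

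There were 31 gene lists, of which 26 with enough tested members were tested by cameraPR of limma 3.58.1 on the signed statistic, two-sided, with a preset inter-gene correlation of 0.01 and adjustment over 78 tests. A correlation could not be estimated without per-sample values, and 0.05 was the alternative. Entries without a statistic (10 with HCC1954 siRNA and 213 with shRNA) were given the quantile of p scaled to the statistic, a treatment chosen after seeing the data. Median log2 ratios of lists were set against 10000 random lists of matched expression. The grouping, tests, gene lists, alternatives and named-gene rule were fixed before the data were examined.

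Genes are named by that rule: TFAP2C and the other AP-2 genes, 8 fixed genes, the 10 largest rises and falls of each genome-wide comparison with at least 1 FPKM in both groups, the 10 shared genes per direction with the largest smallest change, up to 4 called members of each list, the 10 per direction of the HCC1569 table and the 5 per sign with the largest z. Some genes that the rule names are not reported here. Others are named with the remark that they were chosen after their values were seen, or as examples of a listed count.

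The difference, list and overlap tests were run on simulated data. The difference test recovered 2.70%, 44.0% and 74.9% of differences of 1, 2 and 4 log2 units set in 200 of 8634 genes compared between HCC1954 siRNA and shRNA, and 3.08%, 49.0% and 82.0% in 200 of 8907 compared between SKBR3 and HCC1954. With the standard error from the deposited p, recovery was 43.5%, 77.65% and 93.9%, and 55.2%, 84.85% and 96.4%. Simulated noise had the same standard error that the test used, so recovery holds only if that error is right. The list test recovered 83.3% of 60 shifted lists among 9903 SKBR3 genes with 0% of unshifted lists called. These 60 were the same few lists shifted again in each draw of independent normal statistics. The 0% therefore does not cover lists whose genes move together. The overlap test passed in 5.60% of 1000 draws of independent lists among 8907 genes, with genes drawn as if unrelated to each other. Alternatives were a q under 0.01, a 2-fold minimum, a 1 FPKM filter, 1 accession per symbol, a pseudocount of 1 FPKM, centring, accession matching, the standard error from p and the preset correlation. GC content and transcript length came from GENCODE transcripts (96.2% of tested symbols had them), and the trend was removed in 20 GC and 10 length bins, numbers that the written predictions did not state. Analyses ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3. XIST and Y-linked genes were not used here.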

Results

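Expression was measured by RNA sequencing in 3 HER2-positive human breast carcinoma lines, SKBR3, HCC1954 and HCC1569, after knockdown of TFAP2C, the gene of the transcription factor AP-2gamma. The 24 samples fell into 8 groups of 3: a non-targeting control and a TFAP2C knockdown for transient siRNA in each line, and the same pair for a lentiviral shRNA in stable clones of HCC1954. The stated aim was to find AP-2gamma target genes tied to growth and invasiveness. The values used were the authors' pooled FPKM, 1 per entry and group, so no value below has a replicate spread of its own. In the genome-wide comparisons a gene's level is that of 1 RefSeq transcript, unless FPKM is said to be summed. That transcript can hold little of the gene's signal in another comparison. A gene is said to rise, fall or change only where the q-value of the authors' deposited table was under 0.05. The sequencing depth of the samples is unknown. Nothing in the labels says that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

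TFAP2C itself (chromosome 20, 55204362 to 55214339 on the plus strand, GRCh37) fell in each genome-wide comparison. Its level went from 157 to 53.9 FPKM in SKBR3, a 2.92-fold fall, from 92.4 to 22.0 FPKM with siRNA in HCC1954, a 4.20-fold fall, and from 81.0 to 3.46 FPKM with shRNA in HCC1954, a 23.4-fold fall. In the authors' deposited table these falls had q = 4.41e-04, 4.25e-03 and 1.21e-04. The shRNA knockdown group correlated less with its own control (0.748) than SKBR3 control cells did (0.778). The block of 40 neighbouring genes that starts with TFAP2C had a median log2 ratio of -1.16 with shRNA, GC and length trend removed. A change with shRNA, in TFAP2C, ERBB2 or any gene below, therefore cannot be credited to the shRNA alone. The related TFAP2A was listed at 15.7 to 16.7 FPKM in SKBR3 and at 7.10 to 9.85 FPKM with siRNA in HCC1954, neither called, and fell from 21.7 to 2.29 FPKM with shRNA. TFAP2B, TFAP2D and TFAP2E were tested in no table, and the HCC1569 table held no TFAP2C entry.

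ERBB2, the HER2 receptor gene (chromosome 17, 37844167 to 37886679 on the plus strand, GRCh37), fell from 1009 to 541 FPKM in SKBR3 and from 1315 to 16.9 FPKM with shRNA in HCC1954, and was listed at 4205 to 3571 FPKM with siRNA in HCC1954 (q = 0.872 in the authors' deposited table). ERBB3 rose from 47.2 to 58.6 FPKM in SKBR3 and fell from 12.3 to 10.1 FPKM with shRNA. EGFR fell from 13.7 to 9.71 FPKM with shRNA and was not called after siRNA. CDKN1A, a cyclin-dependent kinase inhibitor, rose from 8.59 to 38.8 FPKM with siRNA and from 35.7 to 83.6 FPKM with shRNA in HCC1954, against 4.01 to 3.21 FPKM in SKBR3, which was not called. CDH5, the gene of VE-cadherin, rose from 10.8 to 29.2 FPKM in SKBR3 and fell from 4.04 to 0.559 FPKM with siRNA in HCC1954; with shRNA it fell from 9.59 FPKM to a level listed at 0. IGSF9 was called in none of the 3 tables, HPSE, the heparanase gene, was tested in SKBR3 alone and not called, and ESR1 was tested in none.

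**Figure D1:**
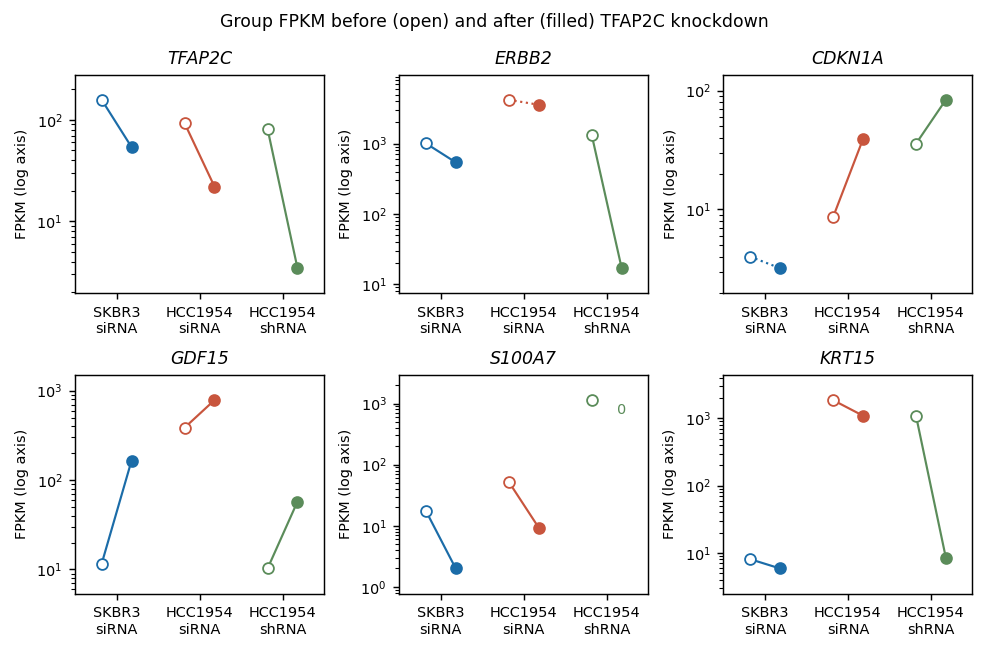
Group FPKM on a log axis for 6 genes, open circles for the control and filled circles for the knockdown of the SKBR3 siRNA, HCC1954 siRNA and HCC1954 shRNA comparisons, joined by a solid line where the change was called and a dotted line where it was not. TFAP2C fell and GDF15 rose in each comparison, and S100A7 is listed at 0 after shRNA, marked by the digit.

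In SKBR3, siRNA against TFAP2C was followed by more rises than falls among stress-response and apoptosis genes and by lower cell-cycle and respiratory chain genes. GDF15, a stress-induced cytokine, rose from 11.6 to 165 FPKM, IGFBP3 from 1.84 to 28.0 FPKM, CCN2 from 10.8 to 104 FPKM, FAM83A from 9.35 to 71.4 FPKM and PHLDA1 from 2.15 to 14.5 FPKM. SERHL2 fell from 55.9 to 2.69 FPKM, S100A4, a calcium-binding protein gene, from 2189 to 388 FPKM, CRAT, the carnitine acetyltransferase gene, from 10.4 to 1.77 FPKM, and S100A7 from 17.6 to 2.00 FPKM. Of 15184 tested entries, 1490 rose and 2324 fell, or 1222 and 2076 of 9903 gene symbols.

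Genes of mitosis and DNA replication fell together in SKBR3. Of 33 tested members of the G2/M and mitosis list, 26 fell and 0 rose (27 and 0 adjusted over the list alone), among them the kinase gene AURKA from 69.4 to 31.8 FPKM, AURKB from 8.45 to 3.27 FPKM and KIF2C from 15.9 to 7.73 FPKM, with adjusted p = 1.23e-07 by limma's cameraPR. Of 30 tested members of the DNA replication and G1/S list, 21 fell and 1 rose (23 and 1 adjusted over the list alone, adjusted p = 1.62e-07 by cameraPR). RRM2, a ribonucleotide reductase subunit gene, fell from 73.6 to 34.2 FPKM and GINS1 from 37.3 to 15.9 FPKM, while CCND1 rose from 112 to 156 FPKM. Nuclear genes of the mitochondrial respiratory chain fell in 22 of 27 cases with 0 rises (23 and 0 adjusted over the list alone, adjusted p = 9.68e-07 by cameraPR), such as ATP5F1B from 681 to 361 FPKM and NDUFV1 from 116 to 60.3 FPKM. In the hypoxia and glycolysis list 14 of 23 fell and 2 rose (15 and 2 adjusted over the list alone). NDRG1 fell from 84.1 to 41.6 FPKM and the glucose transporter gene SLC2A1 from 125 to 73.6 FPKM. This list had adjusted p = 0.0258 by cameraPR and adjusted p = 0.129 at a preset correlation of 0.05.

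In several other lists more genes rose than fell in SKBR3. In the AP-1 and immediate early list 10 of 19 rose and 0 fell (11 and 0 adjusted over the list alone, adjusted p = 5.66e-08 by cameraPR), with ATF3 from 19.3 to 48.7 FPKM and DUSP5 from 4.22 to 12.2 FPKM. Mesenchymal genes rose in 7 of 11 cases with 0 falls (7 and 0 adjusted over the list alone, adjusted p = 7.00e-07 by cameraPR), including fibronectin (FN1) from 2.91 to 9.42 FPKM and TGFB2 from 2.17 to 7.26 FPKM. In the unfolded protein and integrated stress response list 12 of 28 rose and 6 fell (14 and 6 adjusted over the list alone, adjusted p = 1.24e-05 by cameraPR). CHAC1 rose from 5.19 to 43.4 FPKM and the cystine transporter gene SLC7A11 from 1.38 to 7.92 FPKM. Of 19 apoptosis regulators 7 rose and 1 fell (7 and 3 adjusted over the list alone, adjusted p = 4.31e-04 by cameraPR), and the risers included the pro-apoptotic PMAIP1, from 10.3 to 60.6 FPKM, and BMF, from 6.24 to 20.5 FPKM, as well as the inhibitor gene BIRC3, from 2.24 to 7.65 FPKM. Genes listed as p53 targets and CDK inhibitors rose in 6 and fell in 2 of 18 cases (7 and 2 adjusted over the list alone), and NF-kB and inflammatory genes rose in 5 and fell in 1 of 10 (5 and 1 adjusted over the list alone), each with adjusted p = 6.39e-04 by cameraPR. TP53INP1 rose from 1.54 to 4.78 FPKM and ICAM1, an adhesion molecule gene, from 7.46 to 18.2 FPKM. Replication-dependent histone genes rose in 6 and fell in 1 of 11 cases (6 and 1 adjusted over the list alone, adjusted p = 2.95e-03 by cameraPR), with H1-2 from 30.9 to 59.5 FPKM and H2AC6 from 10.6 to 28.9 FPKM. The ERBB receptors and ligands list, with 3 rises and 1 fall among 5 (4 and 1 adjusted over the list alone), had adjusted p = 0.0406 by cameraPR and adjusted p = 0.0912 at a preset correlation of 0.05.

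With siRNA in HCC1954, 6 of 19 basal and myoepithelial genes rose and 5 of 15 epidermal differentiation genes fell. Vimentin (VIM) rose from 3.81 to 12.6 FPKM, tenascin C (TNC) from 1.35 to 10.5 FPKM, CD274, the gene of the checkpoint ligand PD-L1, from 19.97 to 66.7 FPKM. KRT75 rose from 10.1 to 48.8 FPKM and the chromatin protein gene HMGA2 from 1.25 to 4.09 FPKM. KCTD10 fell from 12.6 to 1.00 FPKM, CYP4Z1 from 14.1 to 3.52 FPKM, SPINK8 from 61.2 to 18.9 FPKM, LBP from 82.5 to 28.5 FPKM and PADI2, a peptidylarginine deiminase gene, from 28.8 to 10.7 FPKM. Of 17940 tested entries, 255 rose and 109 fell, or 249 and 104 of 10773 symbols.

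Of 19 tested basal and myoepithelial genes 6 rose and 1 fell in this comparison (9 and 1 adjusted over the list alone, adjusted p = 5.004e-05 by cameraPR). KRT6A rose from 19.1 to 59.1 FPKM, KRT16 from 37.4 to 79.4 FPKM and KRT17 from 357 to 649 FPKM, while KRT15 fell from 1869 to 1097 FPKM and KRT5 was listed at 40.2 to 46.4 FPKM, not called. Epidermal differentiation genes fell in 5 of 15 cases with 0 rises (6 and 0 adjusted over the list alone, adjusted p = 5.68e-03 by cameraPR), among them S100A7 from 52.2 to 9.33 FPKM, S100A8 from 1514 to 630.4 FPKM, S100A9 from 5716 to 3711 FPKM and the transglutaminase gene TGM1 from 6.03 to 2.22 FPKM. Mesenchymal genes rose in 5 and fell in 1 of 15 cases (7 and 1 adjusted over the list alone), with SNAI2, a transcription factor of epithelial-mesenchymal transition, from 6.600 to 13.4 FPKM and THBS1 from 23.1 to 41.4 FPKM. This list had adjusted p = 8.40e-03 by cameraPR and adjusted p = 0.0521 at a preset correlation of 0.05. Invasion and matrix genes rose in 6 and fell in 1 of 19 cases (8 and 1 adjusted over the list alone), with TIMP1, a metalloproteinase inhibitor gene, from 21.4 to 41.6 FPKM, and had adjusted p = 0.0258 by cameraPR and adjusted p = 0.116 at a preset correlation of 0.05. That list holds HPSE, CDH5 and IGSF9, remembered as genes the study followed up in these samples, so it is not independent evidence. Among p53 targets, GADD45A rose from 31.0 to 84.5 FPKM and GDF15 from 386 to 785 FPKM, with 3 rises and 0 falls of 18 (3 and 1 adjusted over the list alone, adjusted p = 0.378 by cameraPR). Of 34 G2/M genes 1 fell, PRC1, from 36.2 to 24.7 FPKM (1 fall and 0 rises adjusted over the list alone, adjusted p = 0.0666 by cameraPR), while the median log2 ratio of the list, -0.22, lay at percentile 0 of 10000 random lists of matched expression. Random lists take no account of correlation between the genes of a list. The columns of this table name only the siRNA, and its line is that in the name of the deposited file.

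Stable shRNA in HCC1954 was followed by changes in most tested genes, with lower HER2 amplicon and inflammatory genes and higher ribosomal protein genes. Keratin 5 (KRT5) fell from 281 to 0.342 FPKM, KRT17 from 320.0 to 0.109 FPKM, LCN2, the gene of lipocalin 2, from 3887 to 2.46 FPKM, CXCL8 (interleukin 8) from 575 to 0.664 FPKM and IGFBP3 from 229 to 4.75 FPKM. KRT19 rose from 19.9 to 634 FPKM, S100A4 from 15.4 to 646 FPKM, and the actin-bundling gene FSCN1 from 4.97 to 159 FPKM. Higher too were the EGFR ligand genes EREG from 1.70 to 152 FPKM and AREG from 5.16 to 131 FPKM, and CKB, a creatine kinase gene, from 2.21 to 159 FPKM. Of 13559 tested entries 4260 rose and 4726 fell, which is 66.3%, or 3468 and 3745 of 9564 symbols. Across 12847 genes, the Spearman correlation of the knockdown group with its own control was 0.748, against 0.778 for SKBR3 control cells with that control and 0.828 for the other HCC1954 control, and this difference stands beside every gene group of this comparison. Levels in those correlations come from separately normalized tables.

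The genes around ERBB2 on chromosome 17 fell in a block after shRNA. In the 17q12 HER2 amplicon list 9 of 11 fell and 1 rose (9 and 1 adjusted over the list alone, adjusted p = 3.17e-05 by cameraPR). GRB7 fell from 30.5 to 0.528 FPKM, PGAP3 from 163 to 2.45 FPKM and ORMDL3 from 1357 to 30.1 FPKM, and MIEN1 from 896 to 22.8 FPKM. The GRB7 entry used was at 1061 FPKM in the siRNA control of HCC1954. Its shRNA values may therefore hold only part of that gene's signal. PSMD3, further along the chromosome, was listed at 97.1 to 96.0 FPKM and was not called. CDK12 fell from 22.97 to 16.7 FPKM and MED1 rose from 16.4 to 30.0 FPKM. MIEN1, PSMD3, CDK12 and MED1 were chosen after their values were seen. PGAP3 and MIEN1 overlap ERBB2 in the annotation, and no source used here states that strand was used in counting, so reads in the overlaps cannot be assigned. With siRNA in HCC1954, 0 of 13 tested members of this list rose or fell (0 and 0 adjusted over the list alone, adjusted p = 0.271 by cameraPR), while their median log2 ratio of -0.24 lay at percentile 0.13 of 10000 random lists of matched expression.

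**Figure D2:**
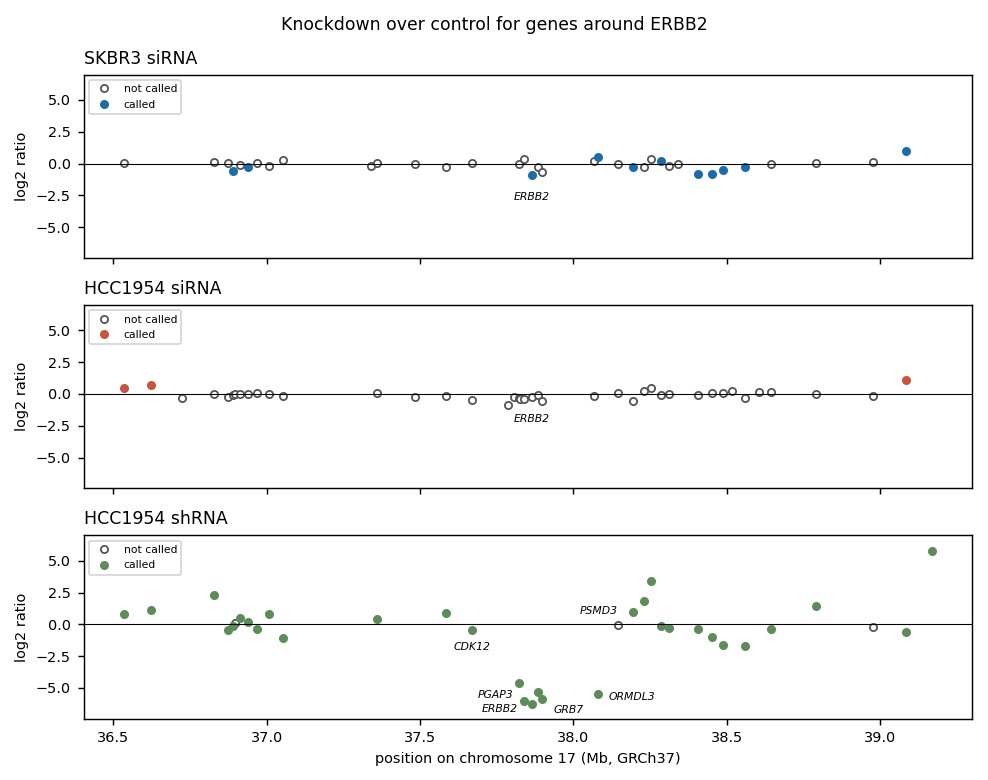
Log2 ratio of knockdown over control FPKM against gene position on chromosome 17 (Mb, GRCh37) in the 3 genome-wide comparisons, filled where called and open where not, with 1 tested gene of the shRNA comparison at 0 FPKM in its control left out. After shRNA, ERBB2, PGAP3, GRB7 and ORMDL3 lie below -5 while PSMD3 lies near 0.

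In several further lists more genes fell than rose after shRNA. NF-kB and inflammatory genes fell in 12 of 16 cases with 0 rises (12 and 0 adjusted over the list alone, adjusted p = 9.07e-06 by cameraPR), with CXCL2 from 39.1 to 0.272 FPKM and ICAM1 from 58.4 to 1.199 FPKM, and CCL2 fell from 246 FPKM to a level listed at 0. Tight junction and desmosome genes fell in 15 and rose in 3 of 20 cases (15 and 3 adjusted over the list alone), with CLDN1, a claudin gene, from 141 to 0.0131 FPKM and TJP1 from 14.8 to 1.80 FPKM. Their list had adjusted p = 6.18e-03 by cameraPR and adjusted p = 0.0540 at a preset correlation of 0.05. Interferon response genes fell in 13 and rose in 3 of 20 cases (13 and 4 adjusted over the list alone), with BST2 from 89.1 to 1.85 FPKM and IFITM1 from 116 to 2.21 FPKM, while ISG15 rose from 43.9 to 124 FPKM. That list had adjusted p = 0.0116 by cameraPR and adjusted p = 0.0822 at a preset correlation of 0.05. Luminal genes fell in 14 and rose in 3 of 18 cases (14 and 3 adjusted over the list alone), with GATA3 from 7.02 to 0.366 FPKM and AGR2 from 22.96 to 0.0439 FPKM, and basal genes fell in 12 and rose in 3 of 17 (12 and 3 adjusted over the list alone). Both lists had adjusted p = 0.0213 by cameraPR and adjusted p = 0.102 at a preset correlation of 0.05. Mesenchymal genes fell in 10 and rose in 4 of 16 cases (10 and 4 adjusted over the list alone), with TGFBI from 177 to 0.0620 FPKM and FN1 from 87.0 to 0.424 FPKM, and retinoid, steroid and xenobiotic enzyme genes fell in 12 and rose in 2 of 16 (12 and 2 adjusted over the list alone), with AKR1B10 from 43.6 to 0.0556 FPKM. These lists had adjusted p = 0.0307 by cameraPR and adjusted p = 0.116 at a preset correlation of 0.05. Keratin, AKR1C and histone genes have close copies between which reads can be split, and their values are uncertain for that reason.

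Ribosomal protein genes rose after shRNA in 31 and fell in 3 of 34 cases (31 and 3 adjusted over the list alone, adjusted p = 2.92e-12 by cameraPR). RPLP0 rose from 159 to 577 FPKM, RPS2 from 533 to 1498 FPKM and RPL32 from 13.7 to 52.3 FPKM. Respiratory chain genes rose in 18 and fell in 3 of 28 cases (18 and 3 adjusted over the list alone), with CYC1, the cytochrome c1 gene, from 77.9 to 198 FPKM, and had adjusted p = 0.0243 by cameraPR and adjusted p = 0.135 at a preset correlation of 0.05. AP-1 and immediate early genes rose in 9 and fell in 6 of 22 cases (9 and 6 adjusted over the list alone), with PHLDA1 from 20.3 to 122 FPKM and EGR1 from 4.14 to 23.8 FPKM upward and JUN from 65.1 to 5.49 FPKM downward. This list had adjusted p = 0.0213 by cameraPR and adjusted p = 0.116 at a preset correlation of 0.05.

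**Figure D3:**
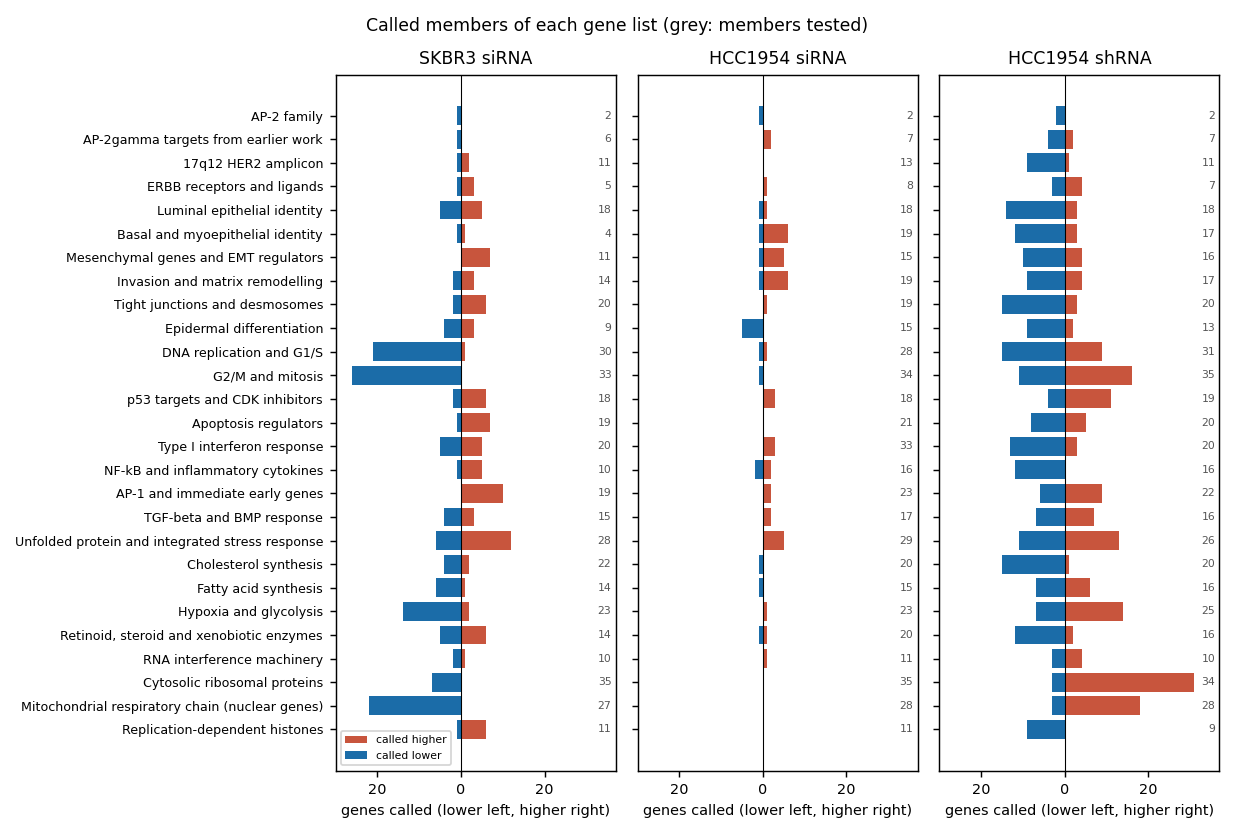
Number of members of each gene list called higher (right, red) and lower (left, blue) after knockdown in the 3 genome-wide comparisons, with the number of members tested in grey. In SKBR3 the G2/M list has 26 falls and 0 rises, and after shRNA in HCC1954 the ribosomal protein list has 31 rises and 3 falls.

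Changes shared by the comparisons were set side by side. Only expression was measured, so a shared change does not show a target of AP-2gamma. The lines covered are SKBR3 and HCC1954 alone, the latter with both siRNA and shRNA. The shRNA knockdown group may differ from its control as a cell population, which can add to the shared genes. GDF15, GADD45A, PHLDA1, ADM (adrenomedullin), the insulin signalling adaptor gene IRS1 and the ubiquitin-like modifier gene ISG15 rose in all 3 genome-wide comparisons. TFAP2C, S100A7, CCL2, KRT4, SUSD2, GLYATL2, EFHD1 and GPR39 fell in all 3. SUSD2 fell from 519 to 244 FPKM in SKBR3, from 34.0 to 12.8 FPKM with siRNA in HCC1954 and from 61.8 to 8.90 FPKM with shRNA, and IRS1 rose from 5.64 to 11.99, 1.37 to 3.004 and 7.29 to 19.6 FPKM in the same order. Among 8053 genes tested in all 3, 16 rose and 32 fell throughout, against 6.66 and 6.79 for independent lists. The siRNA comparisons of SKBR3 and HCC1954 alone shared more calls than independent lists would, as given below. An excess over 6.66 and 6.79 therefore does not show sharing with shRNA.

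Between the siRNA comparisons of SKBR3 and HCC1954, 61 genes rose in both and 42 fell in both among 8907 tested in both, where 21.8 and 17.6 were the counts for independent lists (one-sided Fisher's exact test, adjusted p = 4.56e-14 and 7.92e-09 over 12 tests). In opposite directions, 12 rose in SKBR3 and fell in HCC1954, against 10.7, and 34 the reverse, against 35.9 (exact adjusted p = 0.507 and 0.800). Between siRNA and shRNA in HCC1954, 84 rose in both and 67 fell in both among 8726, against 69.3 and 35.1 (exact adjusted p = 0.0308 and 6.01e-12). A further 102 that rose with siRNA fell with shRNA, against 85.1 (exact adjusted p = 0.0196), while 7 that fell with siRNA rose with shRNA, against 28.6 (exact adjusted p = 1). Between SKBR3 siRNA and HCC1954 shRNA, 274 rose in both and 743 fell in both among 8446, against 356 and 736 (exact adjusted p = 1 and 0.507). Matched by accession, which counts some genes more than once, 789 fell in both among 11548, against 717 (exact p = 1.34e-04, unadjusted). In the opposite directions, 610 that rose in SKBR3 fell with shRNA, against 411 (exact adjusted p = 8.54e-40), and 746 that fell in SKBR3 rose with shRNA, against 638 (exact adjusted p = 5.72e-09). Genes are not independent of each other, so these p-values are descriptions. They test only for an excess of shared calls, so a large one can hide a shortfall. The 274 shared rises and the 7 genes that fell with siRNA and rose with shRNA were fewer than expected (odds ratios 0.652 and 0.175). Across genes, the log2 ratios of SKBR3 siRNA and HCC1954 shRNA had a Spearman correlation of -0.112, without trend removal. It was 0.138 between the siRNA comparisons and 0.0607 between HCC1954 siRNA and shRNA.

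The response of CCN2 differed between the lines, with a rise in SKBR3 and a fall from 41.6 to 28.9 FPKM with siRNA in HCC1954. The test of the difference between log2 ratios passed its threshold in 45 of 8907 genes, among them CCN2, CDH5, GDF15, PMAIP1 and LCN2, which rose from 90.7 to 371 FPKM in SKBR3 and was listed at 1785 to 1456 FPKM with siRNA in HCC1954. Between siRNA and shRNA in HCC1954 it passed in 1188 of 8634 genes, 393 with the higher log2 ratio after shRNA, such as KRT19 and S100A4, and 795 with the lower one, such as THBS1, KRT15 and IGFBP3. With the standard error implied by the deposited p in place of the statistic, the counts were 1104 and 4257.

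In HCC1569, the table held 68 genes, each called the same way with siRNA and with shRNA in HCC1954. In SKBR3, 0 of them were called that way, 31 were called the opposite way and 37 were not called. Of 103 genes with this pattern in the genome-wide comparisons, 68 were held. The table thus describes a selected list without the genes that SKBR3 and HCC1954 share, and its relation to SKBR3 was fixed by that selection. NPDC1 rose from 3.38 to 27.8 FPKM, MROH6 from 1.88 to 15.1 FPKM, SMPDL3B from 1.51 to 13.7 FPKM, S100A9 from 712 to 6118 FPKM and CDKN1A from 23.2 to 41.0 FPKM. DUSP7, a MAP kinase phosphatase gene, fell from 15.6 to 7.30 FPKM, and the tubulin tyrosine ligase gene TTL from 9.02 to 4.56 FPKM. Of 46 tested genes 26 rose and 5 fell. Of these 31, 23 went the way they had gone in HCC1954 and 8 the opposite way, among them S100A9, PLAAT4 and STEAP4, which rose here and fell in HCC1954 (PLAAT4 from 1.58 to 15.7 FPKM and STEAP4 from 3.41 to 18.6 FPKM). Genes higher in HCC1954 rose in 22 and fell in 4 cases here, and genes lower in HCC1954 rose in 4 and fell in 1. A two-sided Fisher's exact test of these counts gave p = 1. With so few falls it cannot tell whether direction in HCC1569 is related to that in HCC1954. CDH5 was listed at 0 in both groups and was not tested.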

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

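The patterns weighed here were chosen after their results were seen, as were their tests and the version with summed FPKM. Each interval given for a pattern, here and in the other observations, is a 95% range over 1000 resamplings of genes. It holds no spread between samples. Values below are differences of log2 ratios that passed the test of the difference, listed because the response differed between 2 comparisons. Between shRNA and siRNA in HCC1954 this held for 1188 genes, and for 48 of 101 compared genes named in the text (69 with the standard error from the deposited p), with the siRNA ratio subtracted from the shRNA ratio.

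Keratin and basal genes were among the lowest: KRT17 -12.38, KRT5 -9.89, KRT6A -7.86, KRT16 -6.83 and KRT15 -6.25, while KRT19 5.90 was among the highest. Matrix and mesenchymal genes gave TNC -13.36, TGFBI -12.06, PMEPA1 -9.46, SNAI2 -7.03, THBS1 -4.83, VIM -4.76 and CCN2 -3.99. In the authors' deposited table the shRNA values of TNC and SNAI2 had q = 0.114 and 0.220, so statistic and p disagree for them and both differences are uncertain. Sizes here depend on knockdown levels near 0: with a pseudocount of 1 FPKM the shRNA log2 ratio of TGFBI was -7.39 in place of -11.48, that of TNC -6.18 in place of -10.40 and that of KRT17 -8.18 in place of -11.51. Cytokine, interferon and secreted genes gave S100A9 -14.09, LCN2 -10.33, CXCL8 -9.62, CXCL2 -7.28, IGFBP3 -6.76, BIRC3 -6.06, IFITM1 -5.85, ICAM1 -5.82 and BST2 -5.43. HER2 amplicon and AP-2 genes gave ERBB2 -6.05, PGAP3 -5.67, TFAP2A -3.72 and TFAP2C -2.48, with MED1 1.01 above 0. Other genes with the lower ratio after shRNA were STEAP4 -12.19, FAM83A -7.71, JUN -3.66, H1-2 -3.64, GPR39 -1.70, PADI2 -1.66, CCND1 -1.52 and SUSD2 -1.39. Genes with the higher ratio after shRNA were HMGA2 5.62, CKB 5.59, S100A4 5.21, FSCN1 5.02, AREG 3.73, EGR1 2.39, DUSP5 2.29, PHLDA1 2.05, SLC7A11 1.496, GDF15 1.46, CYC1 1.40, RPS2 1.28 and ATP5F1B 1.17. Small RNA genes held 1.13% of FPKM in the shRNA control and 2.55% in its knockdown, against 21.7% in the siRNA control of HCC1954, and the effect of this on the shRNA values and on these differences was not tested.

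Between the siRNA comparisons of SKBR3 and HCC1954, 45 genes differed, and 14 of 97 compared genes named in the text (42 with the standard error from the deposited p), with the HCC1954 ratio subtracted. Above 0 were CDH5 4.28, CCN2 3.80, GDF15 2.81, CHAC1 2.76, IGFBP3 2.76, PMAIP1 2.48, LCN2 2.33, SLC7A11 2.24, PHLDA1 2.22, TP53INP1 2.06, FAM83A 1.80 and DUSP5 1.56. Below 0 were BMP7 -2.85 and TTL -1.64.

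The far larger changes after shRNA than after siRNA in HCC1954, as in ERBB2 and KRT5, were weighed against 3 explanations. Cells of another origin under the knockdown label fit the test, since the knockdown group's correlation with its control minus that of SKBR3 with that control was -0.0304 (interval -0.0421 to -0.0191), and -0.0257 with summed FPKM. Altered copy number in those cells also fit, with block medians along the chromosomes spread 2.41 times as widely as in shuffled genes, against 1.10 with siRNA in HCC1954 and 1.09 in SKBR3. A stronger or longer siRNA response failed its test across all genes, where the shRNA and siRNA log2 ratios correlated at 0.0521 (interval 0.0322 to 0.0746). That test cannot exclude it, because siRNA changed few genes (249 rises and 104 falls of 10773 symbols) and noise in the others lowers a correlation. Even the siRNA comparisons of SKBR3 and HCC1954, whose calls overlapped, correlated at only 0.160 with the trend removed. Of 85 genes that fell with siRNA 67 also fell with shRNA, against 35.1 for independent lists, and 7 rose, against 28.6. A shared part among called falls is therefore not excluded. The shRNA values may therefore mix effects of TFAP2C with differences between cell populations, and these tests do not separate a mislabelled culture from a diverged clone.

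The 46 genes called in opposite directions after siRNA in SKBR3 and HCC1954, such as CCN2 and CDH5, were no more than independent lists give (12 against 10.7 and 34 against 35.9), and were weighed against a bias of GC content or transcript length. The 34 genes higher in HCC1954 had a median GC content of 60.9% and the 12 higher in SKBR3 of 51.7%, against 48.6% for all genes tested in both. Removing the GC and length trend left 95.1% of the median difference (interval 84.2 to 103.8), from 1.38 to 1.32 log2 units. The average trend thus accounts for little of it. That trend was small, with 2.44% of the variance of log2 ratios in SKBR3 and 2.31% with siRNA in HCC1954. It could have removed little of a difference of this size in genes picked for opposite calls. The test therefore cannot exclude a GC or length bias particular to these genes. The 95.1% left gives no separate support to a response that depends on the cell line, which stays open. Small RNA genes held 2.21% of FPKM in the SKBR3 control and 21.7% in the HCC1954 siRNA control, a difference between the libraries whose effect was not tested.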

How the results depend on the processing

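Of 95 counts recomputed under alternatives, 65 stayed within 1.5 times the main count and 30 did not. No call changed direction under centring, and the 1 FPKM filter removed no tested entry. Requiring a 2-fold change left 386 rises and 461 falls in SKBR3, 66 and 29 with siRNA and 2161 and 2651 with shRNA in HCC1954, 1 fall in HCC1569, and 15, 27, 78 and 7 shared calls (SKBR3 with HCC1954 siRNA, HCC1954 siRNA with shRNA, SKBR3 siRNA with HCC1954 shRNA, and all 3), where the main counts were 103, 151, 1017 and 48. Symbols with 1 accession alone gave 609 and 943 in SKBR3, 167 and 67 with siRNA and 1559 and 1654 with shRNA, and, in an alternative chosen after seeing the data, 504 calls shared by SKBR3 and shRNA. A log2 ratio of at least 0.5 with a pseudocount left 921 and 1375 in SKBR3. A threshold of 0.01 left 169 and 63 with HCC1954 siRNA, 3 falls in HCC1569, 66, 84 and 26 shared calls (SKBR3 with HCC1954 siRNA, HCC1954 siRNA with shRNA, and all 3) and 764 differences between siRNA and shRNA. Each of these counts follows from fewer entries passing a stricter rule or being used. Matched by accession, the falls shared by SKBR3 siRNA and HCC1954 shRNA passed the overlap test (odds ratio 1.204 against 1.019 by symbol), and the cause was not tested. With the standard error from the deposited p, 4257 genes differed between siRNA and shRNA and 1104 between the lines, because that error is smaller.

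At a preset correlation of 0.05, 15 of 27 list calls were left, because a larger correlation widens the null. Entries without a statistic were first given an unscaled quantile, which gave 28 list calls; the scaled value was chosen after seeing the data and ended the call of the epidermal differentiation list after shRNA (adjusted p = 0.0666 by cameraPR). With the log2 ratio with a pseudocount as the ranked value, 25 lists were called. That version called the epidermal differentiation and histone lists after shRNA (adjusted p = 1.47e-28 and 7.47e-06 by cameraPR) and ended the calls of hypoxia and glycolysis and of ERBB receptors in SKBR3 (adjusted p = 0.227 and 0.164) and of AP-1 and respiratory chain genes after shRNA (adjusted p = 0.304 and 0.227). The cause was not tested.

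Of 689 log2 ratios of named genes, 619 were the same, 68 moved and 2 reversed with FPKM summed over accessions, an alternative chosen after seeing the data: IFITM3 to 0.129 and PFKFB3 to -1.02 after shRNA, where other accessions moved the opposite way. Centring moved 8 and a pseudocount moved 42.

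No paired analysis was possible because the tables hold 1 pooled value per group and no replicate columns. For the same reason the replicate block, leaving out each replicate, DESeq2 and limma on samples were not run. For the HCC1569 table the 1 FPKM filter with a recomputed adjustment, centring and shared symbols were not run. Depth is unknown, and tested entries with low FPKM limit what a missing call means.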

Other observations

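The pattern weighed at the end of this part was chosen after its result was seen, as were its tests and the thresholds for genes gained and lost. The fatty acid synthase gene FASN fell from 429.8 to 261 FPKM in SKBR3, the desaturase gene SCD from 295 to 149.6 FPKM and SREBF1 from 125 to 71.7 FPKM, with 6 falls and 1 rise among 14 tested fatty acid synthesis genes (6 and 2 adjusted over the list alone, adjusted p = 0.146 by cameraPR, median log2 ratio at percentile 1.84 of the random lists). Of 20 cholesterol synthesis genes tested after shRNA 15 fell and 1 rose (15 and 1 adjusted over the list alone, adjusted p = 0.106 by cameraPR, percentile 0.32), with HMGCS1 from 38.7 to 8.09 FPKM. Replication-dependent histone genes fell in 9 of 9 cases after shRNA (9 falls and 0 rises adjusted over the list alone, adjusted p = 0.0666 by cameraPR, percentile 0). In the TGF-beta and BMP response list 7 rose and 7 fell among 16 after shRNA (7 and 7 adjusted over the list alone, adjusted p = 0.961 by cameraPR, percentile 3.87), with BMP4 from 0.896 to 93.1 FPKM upward and PMEPA1 from 248 to 0.325 FPKM downward, while BMP7 fell from 110.0 to 21.6 FPKM in SKBR3. Among genes of the RNA interference machinery AGO2 rose from 6.57 to 11.1 FPKM with siRNA and from 6.14 to 14.6 FPKM with shRNA in HCC1954, and this list had adjusted p = 0.753 and 0.864 by cameraPR.

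Some genes differed between almost no signal and high signal, in either direction, between the shRNA control and knockdown groups. Among 13074 genes with FPKM summed over accessions, 67 were under 0.1 FPKM in the shRNA control and at 10 or more in the knockdown, and 115 the reverse, against 0 and 0 in each siRNA comparison. Between the siRNA control and the shRNA control of HCC1954 the counts were 1 and 2. Such genes were not counted between SKBR3 and HCC1954. There were 54 genes under 0.1 FPKM in both HCC1954 controls and at 10 or more in the shRNA knockdown group. LDHB, a lactate dehydrogenase subunit gene, was at 0 and 0.0721 FPKM in those controls and 462 FPKM in the knockdown, and the same group held the metallothionein gene MT1E at 329.6 FPKM, the glutathione transferase gene GSTP1 at 264 FPKM, the cancer-testis gene MAGEB2 at 189.6 FPKM and the embryonic globin gene HBE1 at 147 FPKM. In SKBR3 control cells LDHB was at 162 FPKM and GSTP1 at 21.2 FPKM, and MT1E, MAGEB2 and HBE1 were at 0.0575, 0.0662 and 0.0299 FPKM. These genes were chosen after their values were seen. Cells of another origin under the knockdown label, weighed above, would also give such a pattern. The genes therefore cannot be read as switched on or off by the knockdown of TFAP2C.

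The genes of the HCC1569 table mostly rose, among them NPDC1, MROH6 and CDKN1A, and technical explanations were weighed. GC content had a Spearman correlation of 0.527 with the log2 ratio over 46 tested genes (interval 0.279 to 0.748, permutation p = 2.50e-04), a result that fits a GC bias between libraries. Transcript length had a correlation of -0.504 (interval -0.718 to -0.217, permutation p = 4.00e-04), which fits a length bias, and GC and length were themselves correlated at -0.468, so the 2 cannot be told apart. The same genes' GC content had a correlation of 0.399 with their HCC1954 siRNA ratio, so selection of these genes may carry part of the trend. No biological explanation was tested for this pattern.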
